A study of Mus musculus with 24 samples.

How the data were processed

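RNA was measured in 24 libraries from crypts of the small intestine of 8 mice. Per the labels, 4 mice were heterozygous (het, control) and 4 homozygous (hom, knockout) for the conditional Setd1a allele on an Lgr5-eGFP-CreERT2 background. They received 1 mg tamoxifen on each of 3 consecutive days, and cells were taken 4 days after induction. Live cells were sorted with EpCAM, CD24 and CD45 antibodies into stem, transit-amplifying (TA) and Paneth fractions, so each animal gave 1 library of each fraction and each of the 6 groups holds 4 libraries. The het animals were BN44, BO27, BO58 and BP03, and the hom animals were BN45, BO25, BO57 and BP04. Low-input cDNA was amplified in 17 cycles and 3 ng of it was tagmented.

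The deposited values are raw counts per gene, which the authors made with featureCounts 2.0.1 from Ensembl 98 gene models on mm10 (GRCm38), after bcl2fastq 2.20.0. Per the file headers, counting was unstranded, used fragments of read pairs and a mapping quality of at least 1, and took no option for multi-mapping or overlapping fragments. The BAM folder was named gsnap, and the aligner version is not given in the sources used here. Because counting was unstranded, a gene and an antisense partner cannot be told apart. The table has 55421 genes and 92 ERCC spike-in sequences, and 0 of its columns belong to no sample. Symbols were matched for 55154 gene IDs and 267 had none, and 106 symbols belonged to more than 1 ID. The reference for symbols, coordinates and sequences was GENCODE M21, on the same build. The ERCC sequences had at most 6 counts in a library and were left out of every test.

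Counts per gene were analysed as deposited by the authors, with no library left out. Total counts ran from 24.73 to 47.05 M per library. A level is given in CPM, as edgeR computes it from the library sizes that TMM scaling gave within that comparison, as mean ± SD of 4 libraries. A control level therefore differs between comparisons, and for Paneth libraries by a wide margin: Gip in het Paneth libraries was at 2721 CPM scaled with stem libraries, 2683 with TA libraries and 2102 with hom Paneth libraries, so such levels are not to be compared across paragraphs. A count of 0 was taken to allow up to 3 counts, and that limit covers counting error only, not capture, amplification or sorting. Sex was read from Xist and the Y-linked genes. All 3 libraries were of the same sex in each of the 8 animals, and each genotype had 2 female and 2 male animals.

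Genes were tested with the edgeR 4.0.16 quasi-likelihood F test after TMM scaling and filterByExpr, at a Benjamini-Hochberg adjusted p below 0.05. Het and hom libraries were compared within each fraction, 4 against 4. Differences between the genotype effects of the fractions were tested as interactions in 1 fit of all 24 libraries in 6 groups, and the fractions were compared with each other in the 4 het animals. The het libraries serve both the genotype comparisons and the comparisons between fractions. Expected counts by chance are 5% of the genes tested. Gene lists were tested on voom log2 values with camera of limma 3.58.1 at a preset correlation between genes of 0.01, with adjustment over the lists of a comparison. Beside it ran camera with an estimated correlation and fry. R was 4.3.3. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

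The 26 lists were COMPASS subunits, intestinal stem cell markers, Wnt targets, the Notch pathway, Paneth, goblet, enteroendocrine, tuft, enterocyte and immune cell markers, stromal and endothelial markers, p53 targets, DNA repair and Fanconi anemia genes, S phase genes and G2/M genes. The others were mitochondrially encoded genes, nuclear oxidative phosphorylation genes, cytosolic ribosomal proteins, fatty acid oxidation and PPAR targets, cholesterol synthesis genes, interferon response genes, MHC class II genes, immediate early and dissociation stress genes, unfolded protein and integrated stress response genes, regenerative and fetal-like genes, and sex-linked genes. Some genes sit in more than 1 list, among them Lgr5, Olfm4, Axin2, Fabp1 and Btg2. The regenerative list names 1 gene by 2 symbols. Too few stromal and endothelial markers passed the filter for a test in stem cells. The count of list members past the threshold is given over all genes tested and again adjusted over the list alone.

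The comparisons, lists, filters, alternatives and the rule for named genes were set before the data were examined. In each direction of a genotype comparison the rule names the 12 genes of largest log2 fold change past the threshold with a mean of at least 5 CPM. It leaves out symbols of Gm and digits, symbols ending in Rik or in -ps with or without digits, and IDs with no symbol. Where none passes, the 5 of smallest unadjusted p are given as values. Up to 4 members of each list with the smallest p are named too, with 5 genes per direction for interactions and control contrasts, and Setd1a, Setd1b, Lgr5, Olfm4, Ascl2, Lyz1, Cdkn1a and Mki67 throughout. From these, the text gives a part, and 1 gene that the rule names is not reported here. Rps13-ps2, Rps13-ps1 and the genes called only with the expression filters added later fall outside the rule and were chosen after their values were seen.

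The neighbouring animal codes BN44 and BN45, BO27 and BO25, BO58 and BO57, and BP03 and BP04 were taken as 4 possible pairs, since each joins a het and a hom animal; the labels do not say that these are litters or batches. Sex matched in 4 of the 4 pairs. After the genotype means were removed, library profiles of the pairs correlated at 0.562, 0.254, 0.168 and 0.411 in stem cells and at 0.530, 0.166, 0.380 and 0.311 in TA cells, each the best partner on both sides. In Paneth cells the values were 0.506, 0.063, 0.361 and 0.187, and 1 het animal had a better partner. A fit with the replicate block of these pairs was an alternative and called 1 gene in stem cells, 0 in TA cells and 0 in Paneth cells. Other alternatives were RLE scaling, no filter, at least 10 counts in 4 libraries, DESeq2 1.42.0, voom with quality weights, 1 fit of all 24 libraries, and leaving out each library or animal in turn. Filters of a mean of at least 5 or 20 CPM, with or without robust empirical Bayes and the block, were chosen after seeing the data.

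The tests were tested on simulated data with the depth and spread of these libraries, with 50 genes changed at each fold. The changed genes all had a mean of at least 5 CPM, so recovery of genes below that level was not measured. No structure of pairs or batches was simulated. In stem cells 2, 32, 76 and 92% of genes changed 1.5, 2, 3 and 4-fold were recovered among 15393 genes, with 7 false calls of 108. In TA cells the shares were 12, 30, 84 and 92% of 15288 genes run, and in Paneth cells 0, 8, 52 and 74% of 15579. Control contrasts gave 2, 30, 78 and 94% for stem against TA, 0, 16, 52 and 70% for Paneth against TA, and 0, 14, 66 and 82% for Paneth against stem. The interactions gave 2, 8, 36 and 62% for stem and TA, 0, 8, 28 and 62% for stem and Paneth, and 0, 2, 46 and 66% for TA and Paneth. A list of S phase genes raised by 0.5 on the log2 scale was called by camera (adjusted p = 7.1e-23, and 0.0071 with an estimated correlation), with 0 other lists called. Each gene was drawn independently there. In the stem libraries the estimated correlation within lists ran from -0.09 (tuft cell markers) to 0.71 (MHC class II genes). The simulation therefore does not show how often camera calls lists of correlated genes.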

Results

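Gene expression was measured in sorted stem, transit-amplifying (TA) and Paneth fractions of small intestinal crypts from 4 het control mice and 4 hom Setd1a knockout mice, 4 days after Cre induction. Library totals were 35.8 ± 9.23 M counts in het and 34.0 ± 4.46 M in hom stem cells. They were 35.1 ± 6.04 and 30.4 ± 2.51 M in TA cells, and 28.5 ± 3.59 and 30.2 ± 4.41 M in Paneth cells. Genes with at least 10 counts numbered 16362 and 16190 in het and hom stem libraries, 16047 and 16094 in TA libraries, and 16381 and 16255 in Paneth libraries on average. In Paneth libraries the 10 most abundant genes took between 18.75% and 57.22% of all counts. On the 4 leading axes of all libraries, holding 40.4%, 7.7%, 4.4% and 4.3% of the variance, Paneth libraries lay apart from stem and TA libraries on the leading axis.

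Setd1a encodes a histone methyltransferase of a COMPASS complex, and it is the gene targeted here. In stem cells its level was 5.93 ± 1.73 CPM in hom (n = 4) and 6.48 ± 1.82 CPM in het (n = 4). The het stem libraries of BN44, BO27, BO58 and BP03 held 4.55, 5.29, 8.15 and 7.91 CPM, and the hom stem libraries of BN45, BO25, BO57 and BP04 held 4.23, 6.86, 7.89 and 4.74 CPM. In TA cells Setd1a stood at 6.07 ± 1.11 in hom and 5.56 ± 1.65 in het. In the same order of animals, the het TA libraries held 3.89, 7.76, 4.84 and 5.76 CPM and the hom TA libraries 5.17, 7.65, 5.48 and 5.98 CPM. In Paneth cells it stood at 4.77 ± 0.952 in hom and 7.41 ± 3.05 in het. The libraries held 5.28, 11.4, 4.81 and 8.13 CPM in the het and 5.87, 5.06, 4.58 and 3.59 CPM in the hom libraries. The log2 fold changes were -0.12 (SE 0.31) in stem, 0.13 (SE 0.27) in TA and -0.64 (SE 0.38) in Paneth cells, and none passed the edgeR threshold (adjusted p = 0.98, 0.99 and 1.00). Setd1b, the closest paralog, stood at 18.3 ± 2.03 in hom and 22.2 ± 2.49 in het stem cells. It stood at 22.5 ± 3.99 and 21.99 ± 4.81 in TA cells, and 18.1 ± 3.32 and 20.5 ± 8.26 in Paneth cells. These counts sum all exons of Setd1a (chromosome 7, 127776670 to 127800122, mm10), so loss of a single exon is not measured by them and the genotype labels were not checked by them. Cre was carried by the Lgr5-eGFP-CreERT2 background, and the share of cells that had lost Setd1a was not measured in any fraction. A lack of calls, as in Paneth cells, therefore cannot be told apart from a lack of deletion.

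**Figure D1:**
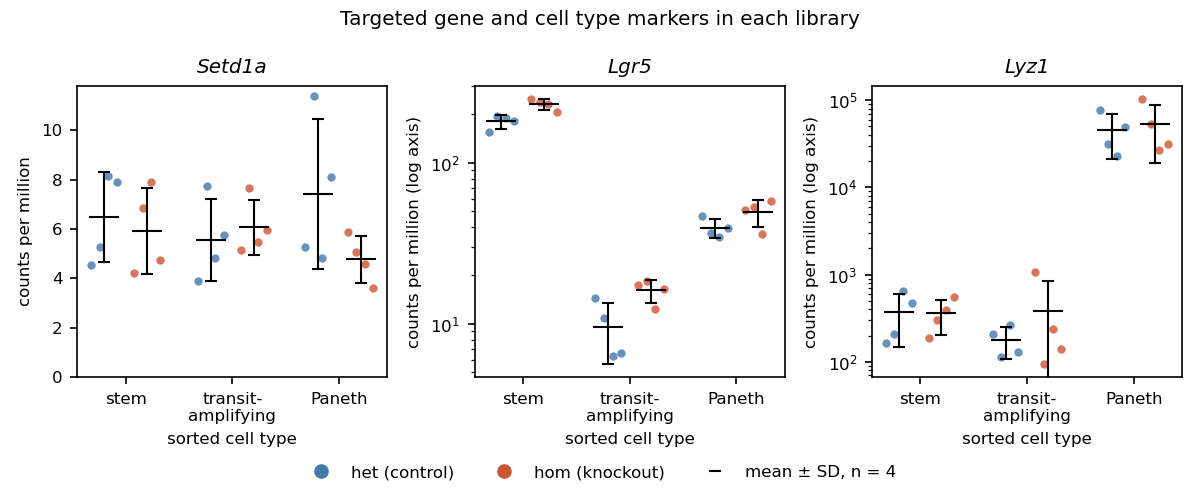
Setd1a, Lgr5 and Lyz1 in each library by fraction and genotype, in CPM with mean ± SD of 4 libraries. Lgr5 and Lyz1 are on a log scale, where the lower end of the hom TA error bar for Lyz1 runs off the axis because the SD exceeds the mean.

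In control animals the sorted fractions differed in markers of several cell types. Lgr5, the R-spondin receptor gene that marks crypt stem cells, stood at 183 ± 16.3 CPM in stem and 9.74 ± 4.06 CPM in TA libraries (n = 4 each), and the stem marker Olfm4 at 31676 ± 3531 and 6777 ± 1724. The BMP co-receptor gene Rgmb stood at 287 ± 8.57 and 57.8 ± 9.32, while the goblet cell gene Spink4 stood at 61.0 ± 16.2 in stem and 898 ± 390 in TA libraries. Gip, an enteroendocrine hormone gene, stood at 2721 ± 313 in Paneth and 0.287 ± 0.176 in stem libraries. Avil and Vav1, of which Avil is a tuft cell gene, stood at 273 ± 37.3 and 150 ± 29.0 CPM in Paneth libraries, against 0.222 and 1.46 in TA libraries. Paneth libraries therefore held enteroendocrine and tuft cell transcripts beside those of Paneth cells. Wherever a result is given for Paneth cells, it belongs to this sorted fraction. Which of its cells carried a transcript or a genotype effect was not measured. The replication gene Mcm6 and the mitotic kinesin gene Kif22 stood at 84.6 ± 4.36 and 9.36 ± 1.76 in Paneth libraries, against 296 ± 39.9 and 66.9 ± 8.42 in TA libraries.

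Between stem and TA libraries of control mice, 435 genes were higher and 578 lower in stem cells of 16182 tested. Among the 5 of smallest p per direction were Rgmb (log2 2.31), Lgr5 (4.23), Soat1 (2.34), Afap1l1 (2.47) and Olfm4 (2.22). Lower in stem cells were Anxa2 (-2.25), Dmbt1 (-2.55), Spink4 (-3.88) and Abat (-1.60), and all of these had an edgeR adjusted p between 0.00030 and 0.00095. Capn9 was the other, at 0.0236 CPM in stem and 14.1 CPM in TA libraries. Paneth libraries had 2813 genes higher and 1908 lower than TA libraries, and 2809 higher and 1791 lower than stem libraries. Of the control contrasts, stem against TA called 249 genes without BO27, 316 without BO58 and 508 without BP03 of its 1013, Paneth against TA 2810 without BP03 and 2922 without BN44 of 4721, and Paneth against stem 2870 without BN44 of 4600. With the animal as replicate block edgeR called 1848 genes between stem and TA libraries (824 higher, 1024 lower), 4714 between Paneth and TA and 4191 between Paneth and stem libraries, and DESeq2 without it called 2231, 7167 and 6983. Stem cell markers were higher in stem than in TA cells (camera adjusted p = 2.6e-31; adjusted p = 0.035 with an estimated correlation), as were Wnt targets (6.8e-13; 0.035). Tuft cell markers were higher in Paneth than in TA libraries (camera adjusted p = 8.2e-18, or 0.049 with an estimated correlation) and than in stem libraries (1.9e-19, or 0.030). Paneth cell markers (6.5e-16 against TA; 0.23 with an estimated correlation) and enteroendocrine markers (2.2e-10; 0.23) were past the threshold only at the preset correlation. The estimated correlation thus missed Paneth cell markers in the Paneth fraction. A list that does not pass with it in a genotype comparison is therefore not shown to be unchanged. S phase genes were lower in Paneth than in TA cells by camera (adjusted p = 1.3e-18; 0.098 with an estimated correlation), as were G2/M genes (4.1e-19; 0.090).

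In stem cells, Cbr4, which encodes a reductase of mitochondrial fatty acid synthesis, fell to 7.23 ± 1.93 CPM in hom from 34.8 ± 3.64 in het (n = 4 each), with 4 of 4 hom libraries under all 4 het libraries. Sdhc, a subunit gene of succinate dehydrogenase, stood at 142 ± 10.5 in hom and 261 ± 23.99 in het, and Ndufv1, of respiratory complex I, at 172 ± 20.96 and 276 ± 28.2. Palb2, whose product joins BRCA1 to BRCA2 in repair, stood at 4.31 ± 2.09 against 13.9 ± 3.71. Among the genes with higher values in hom were the tight junction gene Cldn8 (41.5 ± 7.85 against 12.7 ± 4.21), the annexin gene Anxa3 (8.99 ± 1.49 against 1.97 ± 0.747) and the p53 target Ephx1, an epoxide hydrolase gene (89.4 ± 27.3 against 39.0 ± 6.06). By edgeR 0 genes were higher and 2 lower in hom of 16056 tested, with 1081 at an unadjusted p under 0.05 (443 higher, 638 lower; 803 expected by chance), and DESeq2 called 80 higher and 197 lower. The 2 were Cbr4 (log2 -2.27, SE 0.23, adjusted p = 0.013; chromosome 8, 61487734 to 61506694, mm10) and the pseudogene Rps13-ps2 (adjusted p = 0.0060), whose counts are uncertain. With the replicate block of the animal pairs the Cbr4 call ended (adjusted p = 0.079), as it did on leaving out any of BN44, BN45, BO27, BO57, BO58 or BP04 (adjusted p between 0.062 and 0.10). For the others the edgeR adjusted p was 0.096 for Sdhc, Cldn8 and Anxa3, 0.16 for Ephx1, 0.19 for Ndufv1 and 0.20 for Palb2. After a filter at a mean of 5 CPM, chosen after seeing the data, edgeR called Cbr4 (adjusted p = 0.0034; 0.0028 with the block), Sdhc and Cldn8 (0.036; 0.010) and Anxa3 (0.039; 0.012). They were among 18 genes, or 128 with the block, where Ephx1 (0.034), Ndufv1 (0.012) and Palb2 (0.025) passed too.

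Stem cell identity and cell cycle genes in hom stem cells held these values. Lgr5 stood at 231 ± 17.7 CPM in hom and 181 ± 17.6 in het, Ascl2, a transcription factor gene of stem cells, at 111 ± 10.0 and 108 ± 29.7, and Mki67, a proliferation marker, at 169 ± 19.6 and 206 ± 49.4. The p53 targets Ccng1 (cyclin G1), Plk2 (a polo-like kinase) and Cdkn1a (p21) stood at 188 ± 25.4, 40.3 ± 10.6 and 15.4 ± 3.01 in hom and at 115 ± 21.9, 12.6 ± 8.11 and 9.60 ± 4.95 in het. Clu, a marker of regenerating crypts, stood at 19.4 ± 16.0 in hom and 2.79 ± 2.69 in het. The log2 fold changes were 0.35 for Lgr5, 0.04 for Ascl2, 0.26 for Olfm4, -0.28 for Mki67, 0.70 for Ccng1, 1.67 for Plk2, 0.68 for Cdkn1a and 2.78 for Clu. None passed the edgeR threshold (adjusted p = 0.64 for Lgr5, 0.28 for Ccng1, 0.34 for Plk2, 0.80 for Cdkn1a and 0.43 for Clu). Enterocyte transcripts differed among het stem libraries: Fabp1 stood at 214 and 200 CPM in BO27 and BP03 against 13.6 and 21.2 in BN44 and BO58, and at 22.6 ± 14.4 in hom. Lyz1 of Paneth cells stood at 359 ± 155 in hom and 374 ± 228 in het stem cells.

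**Figure D2:**
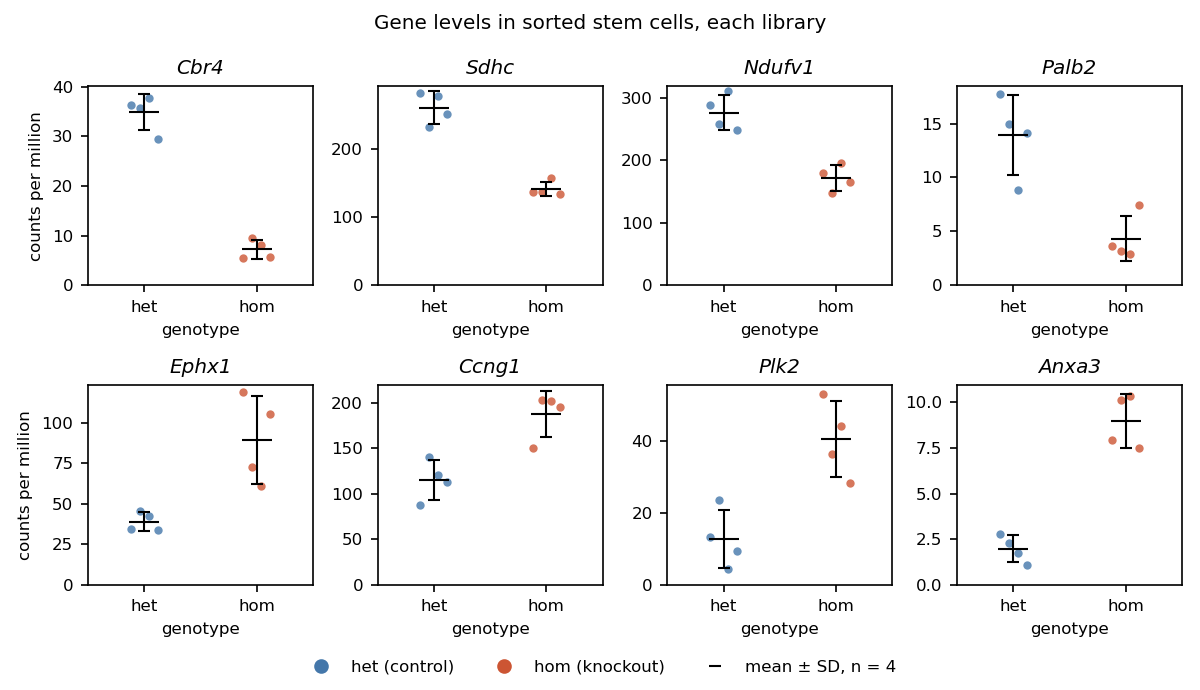
Cbr4, Sdhc, Ndufv1, Palb2, Ephx1, Ccng1, Plk2 and Anxa3 in each het and hom stem library, in CPM. Of these genes only Cbr4 passed the edgeR threshold, and with the replicate block it did not (adjusted p = 0.079; 0.0028 with the block after a filter at 5 CPM chosen after seeing the data).

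As groups, p53 targets were higher in hom stem cells, with 27 of 37 tested members of positive sign and a median log2 fold change of 0.15 (camera adjusted p = 0.011; adjusted p = 0.66 with an estimated correlation). Nuclear oxidative phosphorylation genes were lower, with 38 of 47 negative and a median of -0.17 (camera adjusted p = 3.5e-05; adjusted p = 0.70 with an estimated correlation). In a comparison of libraries chosen after seeing the data, the share of counts from mitochondrially encoded genes was 16.1 ± 2.72% in hom and 13.97 ± 2.69% in het stem libraries and higher in hom in 4 of 4 pairs (exact permutation p = 0.34 over the 8 libraries). That of pseudogenes was 8.06 ± 0.379% and 9.02 ± 0.451% and lower in 4 of 4 pairs (exact permutation p = 0.057), and that of the 10 most abundant genes was higher in 4 of 4 (exact permutation p = 0.086). With sign changes within pairs each exact permutation p was 0.125, the smallest that 4 pairs can give. Of the oxidative phosphorylation genes, Atp5e of ATP synthase stood at 117 ± 6.38 against 185 ± 29.1 CPM. Cytosolic ribosomal proteins were lower, with 41 of 49 negative (camera adjusted p = 0.00034; 0.70 with an estimated correlation), as were enterocyte markers, with 21 of 28 negative (0.0084; 0.79). Regenerative and fetal-like genes were higher, with 9 of 15 positive (camera adjusted p = 0.0084; 0.70 with an estimated correlation). By camera the p53 call ended without BN45 (0.052), that of enterocyte markers without BO27 (0.20) or BP03 (0.095), and that of regenerative genes without BN45 (0.069) or BO27 (0.15). Over all genes, 0 members of any list passed by edgeR, and adjusted over the list alone 3 p53 targets and 2 regenerative genes were higher and 5 oxidative phosphorylation genes and 1 DNA repair gene were lower. DNA repair and Fanconi anemia genes had 33 of 49 members of negative sign (camera adjusted p = 0.071), among them Fancg at 4.77 ± 0.981 against 8.76 ± 1.76 CPM and Prkdc, the DNA-PK kinase gene, at 9.38 ± 3.36 against 18.3 ± 5.97. By fry for changes in either direction, DNA repair genes (adjusted p = 0.013), p53 targets (0.047) and oxidative phosphorylation genes (0.047) passed, and by directional fry 0 lists did.

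The other lists were not past the camera threshold in stem cells. Adjusted p was 0.14 for stem cell markers, 0.68 for Wnt targets, the Notch pathway, COMPASS subunits, G2/M genes, cholesterol synthesis genes and enteroendocrine markers, and 0.80 for S phase genes. It was 0.47 for Paneth, 0.75 for goblet, 0.55 for tuft and 0.91 for immune cell markers, 0.17 for interferon response genes, 0.91 for MHC class II and sex-linked genes, 0.72 for mitochondrially encoded genes and 0.60 for fatty acid oxidation. Immediate early genes had 0.13 and the unfolded protein response 0.14.

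In TA cells, Coq9, needed for coenzyme Q synthesis, stood at 56.7 ± 7.17 CPM in hom and 116 ± 7.92 in het (n = 4 each), with 4 of 4 hom libraries under all het libraries. The zinc finger gene Zfp512 stood at 6.61 ± 0.478 in hom and 16.2 ± 2.42 in het, and Ccdc91, of Golgi transport, at 11.3 ± 4.15 and 31.6 ± 4.18. Ephx1 stood at 72.9 ± 16.1 in hom and 29.9 ± 4.46 in het, and the Wnt feedback gene Axin2 at 15.1 ± 2.42 and 8.05 ± 2.28. The Fanconi anemia gene Fanci stood at 2.08 ± 0.809 in hom and 5.70 ± 2.08 in het. By edgeR 0 genes passed of 15925 tested, with 942 at an unadjusted p under 0.05 (464 higher, 478 lower; 796 expected by chance), and DESeq2 called 47 higher and 74 lower. The edgeR adjusted p was 0.098 for Coq9 (log2 -1.03), Zfp512 (-1.30) and Ephx1 (1.29), 0.25 for Ccdc91 (-1.48) and 0.34 for Tvp23b (-0.80). At a mean of 5 CPM, chosen after seeing the data, edgeR called 4 genes: Coq9 (adjusted p = 0.028; 0.031 with the replicate block), Ephx1 (0.033; 0.031) and the pseudogenes Rps13-ps2 and Rps13-ps1, whose counts are uncertain. Without that filter the edgeR adjusted p was 0.37 for Ufl1 (-1.09), 0.47 for Colca2 (1.02) and Ndufa1 (0.55) and 0.49 for Cttnbp2 (0.94). Rgmb stood at 81.8 ± 7.31 in hom and 56.9 ± 9.22 in het TA cells, and Lgr5 at 16.2 ± 2.67 and 9.57 ± 3.92. In the same order, Ascl2 stood at 33.2 ± 5.57 and 25.8 ± 10.2, Cdkn1a at 45.0 ± 9.40 and 39.0 ± 14.1, and Mki67 at 197 ± 35.6 and 199 ± 42.0. Lyz1 of Paneth cells stood at 386 ± 460 in hom and 178 ± 71.0 in het, and Gip at 28.3 ± 52.1 and 0.355 ± 0.386, each with its highest value in the hom TA library of BN45.

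As groups, cytosolic ribosomal proteins were higher in hom TA cells, with 48 of 49 members of positive sign and a median log2 fold change of 0.24 (camera adjusted p = 6.4e-11; adjusted p = 0.54 with an estimated correlation). Rpl32 stood at 1160 ± 194 CPM in hom and 785 ± 132 in het. Intestinal stem cell markers were higher, with 24 of 26 positive and a median of 0.34 (camera adjusted p = 1.2e-06; adjusted p = 0.54 with an estimated correlation). So were Wnt targets, which share several of those genes (15 of 16 positive; camera adjusted p = 0.0014; 0.55 with an estimated correlation). S phase genes were lower, with 36 of 40 negative and a median of -0.23 (camera adjusted p = 1.2e-06; adjusted p = 0.55 with an estimated correlation). Among them were the licensing gene Cdc6 at 26.3 ± 3.85 against 41.5 ± 6.03 CPM and the checkpoint gene Clspn at 17.9 ± 1.94 against 24.7 ± 4.24. DNA repair and Fanconi anemia genes were lower, with 37 of 49 negative (camera adjusted p = 0.0032; 0.54 with an estimated correlation), and p53 targets higher, with 28 of 38 positive and Ccng1 at 173 ± 11.6 against 129 ± 13.2 (0.0058; 0.54). Unfolded protein response genes were lower, with 15 of 21 negative (camera adjusted p = 0.015, or 0.63 with an estimated correlation). A correction for GC content and gene length, made in the fit with the replicate block, ended that call (camera adjusted p = 0.0090 before and 0.12 after). By camera the p53 call ended without BN45 (0.051) or BO25 (0.053), and that of unfolded protein response genes without BN44 (0.066), BO57 (0.084), BP03 (0.30) or BP04 (0.11). Over all genes 0 members of any list passed by edgeR, and adjusted over the list alone 1 p53 target was higher, and 1 oxidative phosphorylation gene was higher and 2 were lower. By fry only p53 targets passed, for changes in either direction (adjusted p = 0.0035).

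The other lists were not past the camera threshold in TA cells. Adjusted p was 0.16 for COMPASS subunits, 0.27 for the Notch pathway, 0.43 for G2/M genes and 0.97 for nuclear oxidative phosphorylation genes. Among markers of other cells it was 0.056 for Paneth, 0.43 for goblet and enteroendocrine, 0.48 for tuft, 0.33 for enterocyte, 0.63 for immune and 0.97 for stromal and endothelial genes. Cholesterol synthesis genes had 0.055, interferon response genes 0.12, immediate early genes 0.27, regenerative genes 0.92 and sex-linked genes 0.75. Mitochondrially encoded, fatty acid oxidation and MHC class II genes had 0.43. With the replicate block, Paneth cell markers (camera adjusted p = 0.037) and cholesterol synthesis genes (0.033) passed. After a correction for GC content and gene length in that fit, neither did (0.12 for both).

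In Paneth cells, the ER isomerase gene Fkbp9 stood at 7.49 ± 1.79 CPM in hom and 16.9 ± 3.22 in het (n = 4 each), and the transcription factor gene Nfatc3 at 19.7 ± 2.10 and 32.3 ± 1.93. The Ras exchange factor gene Sos1 stood at 25.8 ± 5.27 and 44.9 ± 6.35, and the deubiquitinase gene Usp31 at 2.92 ± 1.14 and 9.61 ± 4.32. Among genes with higher values in hom, the tubulin ligase gene Ttll4 stood at 13.96 ± 3.18 against 7.28 ± 0.263 and the zinc finger gene Zfp867 at 14.5 ± 3.16 against 4.26 ± 2.54. Lyz1, the lysozyme gene of Paneth cells, stood at 53584 ± 34717 in hom and 45487 ± 24382 in het. By edgeR 0 genes passed of 16108 tested, with 368 at an unadjusted p under 0.05 (148 higher, 220 lower; 805 expected by chance), and DESeq2 called 12 higher and 15 lower. The log2 fold changes were -1.17 for Fkbp9, -0.71 for Nfatc3, -0.80 for Sos1, -1.73 for Usp31 and -0.97 for Vwa5a. They were 0.94 for Ttll4 and Ogdhl, 1.76 for Zfp867, 1.13 for Zfp667 and 1.01 for Zfp26, each at an edgeR adjusted p of 1.00. Cdkn1a stood at 167 ± 31.2 in hom and 152 ± 32.2 in het Paneth cells, and Lgr5 at 49.5 ± 9.29 and 39.4 ± 5.32. Olfm4 stood at 4143 ± 1730 and 3027 ± 508, Ascl2 at 25.8 ± 6.38 and 22.4 ± 3.05, and Mki67 at 42.9 ± 9.04 and 52.7 ± 4.93. Dclk1, a tuft cell gene, stood at 585 ± 222 in hom and 709 ± 146 in het Paneth libraries, scaled here with each other alone.

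As groups, Paneth cell markers were higher in hom Paneth cells, with 21 of 26 members of positive sign and a median log2 fold change of 0.62 (camera adjusted p = 0.011; adjusted p = 0.91 with an estimated correlation). The call ended without BN45 (camera adjusted p = 0.88) or BO25 (0.065), and without BO58 the direction reversed (0.52). In the het Paneth library of BO58 the 10 most abundant genes took 18.75% of counts. The defensin gene Defa24, 1 of a family of near-identical copies whose counts are uncertain, stood at 13153 CPM there, at 102677 to 197539 in the other het and at 65567 to 426857 in the hom libraries. Cytosolic ribosomal proteins (41 of 49 positive; 0.00063) and nuclear oxidative phosphorylation genes (35 of 47 positive; 0.00095) were higher and interferon response genes lower (18 of 25 negative; 0.011) by camera at the preset correlation, each at an adjusted p of 0.91 with an estimated correlation. The interferon call ended with the replicate block (camera adjusted p = 0.058) and without BO58 (0.054), BP03 (0.099) or BP04 (0.31), and that of ribosomal proteins without BO58 (0.57). Over all genes and over each list alone, 0 members passed by edgeR in Paneth cells, and fry called 0 lists. The other lists were not past the camera threshold, with an adjusted p of 0.084 for COMPASS subunits. It was 0.29 for stem cell markers, p53 targets, MHC class II, stromal and cholesterol synthesis genes, 0.22 for Wnt targets and regenerative genes, and 0.31 for DNA repair genes. For the Notch pathway and tuft cell markers it was 0.37, for S phase genes 0.29, for G2/M genes and goblet markers 0.46, and for enteroendocrine markers 0.71. The last were 0.53 for enterocyte, 0.88 for immune and sex-linked, 0.32 for mitochondrially encoded, 0.75 for fatty acid oxidation, 0.40 for unfolded protein response and 0.92 for immediate early genes.

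**Figure D3:**
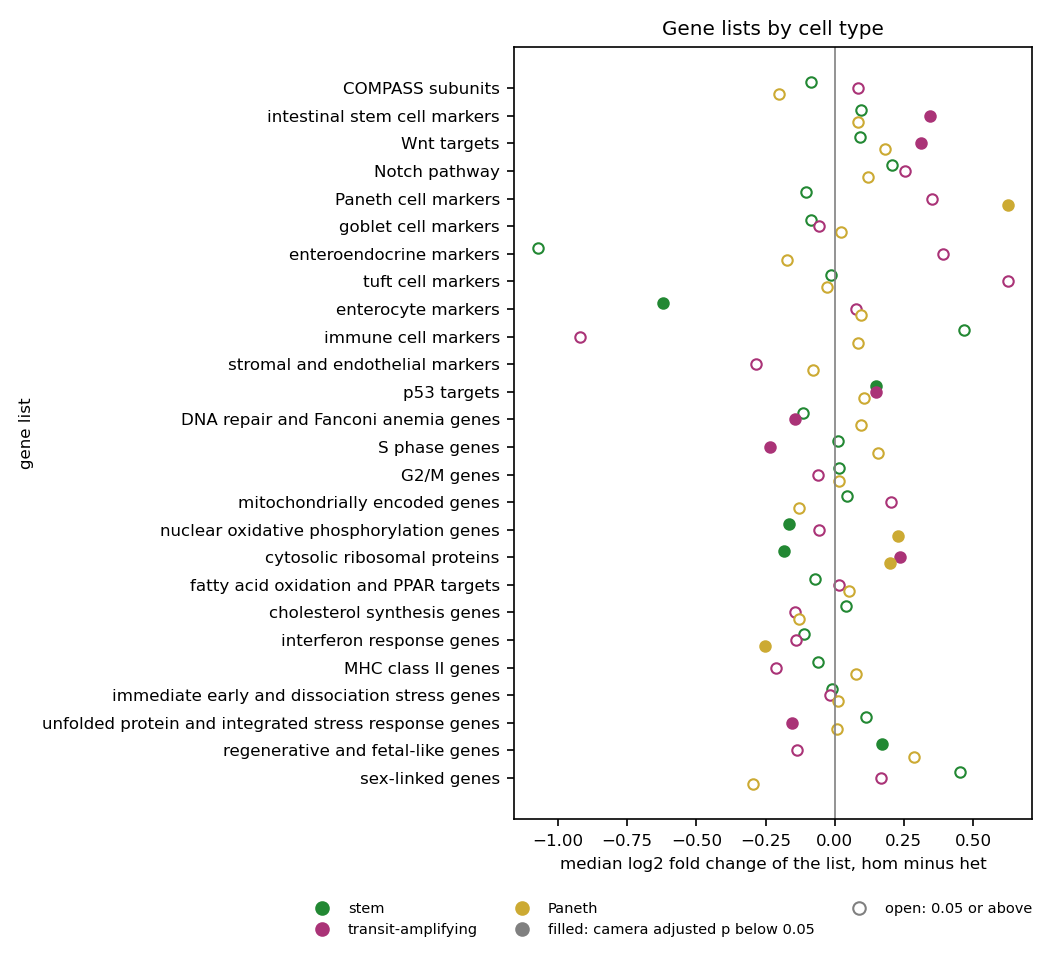
Median log2 fold change, hom against het, of each gene list in stem, TA and Paneth cells. Filled points are lists past the camera threshold at the preset correlation; none passed with an estimated correlation.

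The effect of genotype was also compared between fractions. Cyp2c55, a cytochrome P450 gene (chromosome 19, 39007019 to 39042693, mm10), stood at 0.0904 ± 0.110 CPM in het and 12.6 ± 8.94 in hom Paneth cells (n = 4 each), with all 4 hom libraries above all het libraries. In TA cells it stood at 7.61 ± 3.92 in het and 7.77 ± 2.42 in hom, and in stem cells at 17.9 ± 12.6 and 24.3 ± 12.9. The interaction of TA and Paneth cells called this gene alone of 19396 (edgeR adjusted p = 0.023), with 965 genes at an unadjusted p under 0.05, and DESeq2 called 31. The Cyp2c55 call was kept without BO58 and ended on leaving out any of the other 7 animals. Cyp2c55 stood at 5.09, 12.96, 25.06 and 7.34 CPM in the hom Paneth libraries of BN45, BO25, BO57 and BP04. The enterocyte marker Cyp3a11 ranked alike there (3.57, 19.3, 203 and 10.4, scaled within Paneth libraries). In het BO27, Cyp3a11 was at 10.9 and Cyp2c55 at 0.138. Of 30 enterocyte markers, 17 were positive and 13 negative in hom Paneth cells. Whether enterocyte transcripts account for the Cyp2c55 levels was not tested. Between stem and TA cells edgeR called 0 genes with 767 at an unadjusted p under 0.05, and DESeq2 called 19. Between stem and Paneth cells edgeR called 0 with 1219, or 2 genes with each animal as a replicate block, and DESeq2 called 59. Chance would give 970 at an unadjusted p under 0.05. For Cbr4 the difference between the stem and Paneth effects was -2.23 (edgeR adjusted p = 0.23), for Coq9 that between TA and Paneth was -0.87 (0.76), and for Ccdc91 it was -1.74 (0.42).

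Ribosomal protein genes had lower genotype effects in stem than in TA cells (camera on the interaction, adjusted p = 2.2e-12; adjusted p = 0.76 with an estimated correlation) and than in Paneth cells (2.9e-08; 0.90). S phase genes had higher effects in stem than in TA cells (camera adjusted p = 0.00069; 0.79 with an estimated correlation), and stem cell markers (0.019; 0.79), enterocyte markers (0.0013; 0.79) and oxidative phosphorylation genes (0.017; 0.87) lower ones. Unfolded protein response genes had higher effects in stem than in TA cells (0.0013; 0.79). For p53 targets the effects in stem and TA cells were not told apart (camera adjusted p = 0.93), nor were those of DNA repair genes (0.64) and Wnt targets (0.061). Against Paneth cells, oxidative phosphorylation genes were lower in stem (camera adjusted p = 7.7e-08; 0.90 with an estimated correlation) and in TA cells (0.0015; 0.60). S phase genes (0.00031; 0.60) and DNA repair genes (0.0068; 0.60) had lower effects in TA than in Paneth cells by camera, and stem cell markers (0.021; 0.60), tuft cell markers (0.017; 0.60) and COMPASS subunits (0.0068; 0.60) higher ones. All list tests on the interactions took the libraries of an animal as independent. They were not repeated with the animal as a block or with an animal left out.

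Among processed pseudogenes of the ribosomal protein gene Rps13, Rps13-ps2 was 1 of the 2 genes past the edgeR threshold in stem cells (adjusted p = 0.0060), while in TA cells Rps13-ps1 and Rps13-ps2 had an adjusted p of 0.098 and in Paneth cells of 1.00. Rps13-ps2 (chromosome 7, 88530446 to 88530898, mm10) stood at 24.4 ± 4.84 CPM in hom and 104 ± 10.9 in het stem cells, 24.4 ± 6.28 and 72.2 ± 9.58 in TA cells, and 11.7 ± 3.76 and 40.0 ± 17.0 in Paneth cells. Rps13-ps1 (chromosome 8, 87047689 to 87048226) stood at 139 ± 18.3 in hom and 90.6 ± 11.0 in het stem cells, 154 ± 27.7 and 65.9 ± 9.58 in TA cells, and 73.1 ± 17.9 and 35.2 ± 14.9 in Paneth cells. Rps13 itself stood at 13.8 ± 1.85 in hom and 13.2 ± 1.59 in het stem cells. Of the counts of both pseudogenes, Rps13-ps2 held 12.3 to 15.8% in the 12 hom libraries and 50.9 to 54.7% in the 12 het libraries, each set from 4 animals. The pseudogenes share 72.9% and 70.0% of the 15-base words of Rps13 for Rps13-ps1 and Rps13-ps2, so the source of each read is uncertain.

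**Figure D4:**
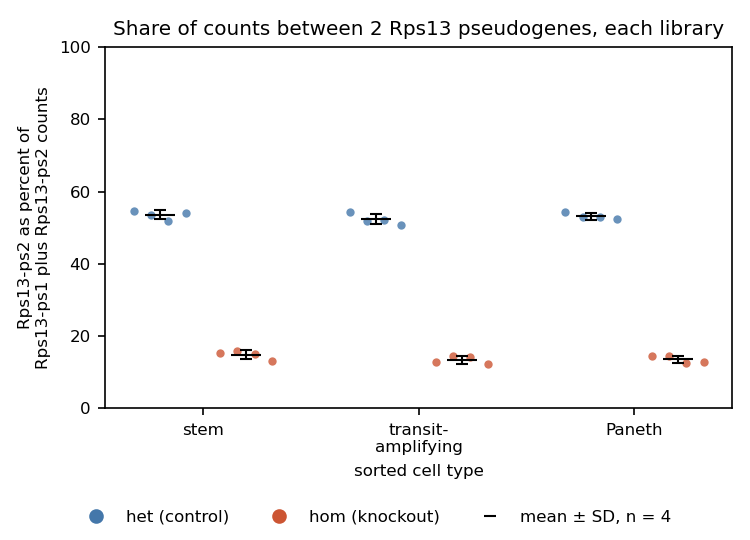
Rps13-ps2 as a percent of the counts of Rps13-ps1 and Rps13-ps2 together, in each of the 24 libraries by fraction and genotype. Reads of near-identical copies are assigned with uncertainty.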

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

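No test in this part was chosen after a result was seen, but the groups searched for a library far from the others were those of the genes whose levels are given here and of the cell marker scores. Of 212 groups of 4 libraries, 8 had such a library; chance alone sets apart about 1 group in 20, or 11 of these.

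Among hom stem libraries, Sdhc was at 157 CPM in BO57 with the others between 135 and 138, Palb2 at 7.41 CPM in BP04 with the others between 2.95 and 3.66, and Ccng1 at 150 CPM in BN45 with the others between 195 and 203.

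Lyz1 was at 1070 CPM in the hom TA library of BN45 with the others between 95.02 and 241, and Gip was at 106 CPM in the same library with the others between 0 and 6.83. The enteroendocrine marker score, a mean log2 of CPM plus 1, was 1.45 in the het stem library of BN44 with the others between 0.42 and 0.58. The tuft cell score was 0.91 in the het TA library of BO58 with the others at 0.70, and the immune cell score was 0.82 in the hom stem library of BO25 with the others between 0.12 and 0.22.

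The genotype effect on Cyp2c55 differed between TA and Paneth cells (log2 0.03 and 7.12; edgeR interaction, adjusted p = 0.023), where the fitted Paneth effect rests on het libraries between 0 and 0.224 CPM and sets no bound on the fold. That call was kept without BO58 and ended on leaving out any of the other 7 animals, with 0 genes called without BN45, BO25, BO27, BO57, BP03 or BP04 and 2 others without BN44. Outside the gene counts, ERCC spike-in sequences had 6 counts in the hom Paneth library of BO25, above the 3 counts that a count of 0 allows.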

How the results depend on the processing

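Alternatives that require a mean of at least 5 or 20 CPM, with or without robust empirical Bayes and the replicate block, were chosen after seeing the data. The stem cell calls of 2 genes were kept, both of them, with RLE scaling, no filter, at least 10 counts in 4 libraries, DESeq2, voom with quality weights and 1 fit of all 24 libraries. The number of calls depended on the tool. DESeq2 called 277 genes in stem, 121 in TA and 27 in Paneth cells. The 243, 110 and 22 of these that edgeR tested all had the same sign and an unadjusted p under 0.05 by edgeR. For the interactions DESeq2 called 19 (stem and TA), 59 (stem and Paneth) and 31 (TA and Paneth) genes, and for the control contrasts 2231 (stem and TA), 7167 (Paneth and TA) and 6983 (Paneth and stem). A single fit of all 24 libraries called 8, 1 and 2 genes in stem, TA and Paneth cells, and no filter called 8 in Paneth cells and 1 for the interaction of stem and Paneth cells. The replicate block gave 1 gene in stem cells (Cbr4 at an adjusted p of 0.079), 2 for the interaction of stem and Paneth cells and 1848 for control stem against TA. For Paneth against TA it called 4714 genes, 4217 of them shared, and for Paneth against stem 4191, with 3872 shared. It ended the call of interferon response genes in Paneth cells, added 2 lists in TA cells and changed the call of no other list. The cause was not tested for any of these.

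After the filter at 5 CPM, 18 genes were called in stem and 4 in TA cells. The block made these 128 and 5, robust estimation 28 and 4, and both together 141 and 5. At 20 CPM the counts were 27 and 4, 130 and 8, 27 and 5, and 160 and 91, and in Paneth cells all 8 settings called 0. Fewer genes were tested there: 10336 in stem cells at 5 CPM, where Sdhc and Foxred1 (both at an adjusted p of 0.036) and Mrpl11 (0.049) were among those lower and Cldn8 and Anxa3 were higher. With an estimated correlation camera called 0 lists in stem, 0 in TA and 0 in Paneth cells, directional fry 0, 0 and 0, and fry for either direction 3, 1 and 0. No filter moved the median log2 fold change in Paneth control contrasts by over 0.1, to 0.94 against TA and 0.85 against stem cells.

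Leaving out each library in turn gave 0 to 3 genes in stem cells: 0 without BN45, BO57 or BO58, 1 without BN44, BO27 or BP04, 2 without BP03 and 3 without BO25. Cbr4 in stem cells then kept its direction (log2 -2.43 to -2.16) with an edgeR adjusted p from 0.021 without BO25 to 0.10 without BO58. TA and Paneth cells stayed at 0 genes. The stem and TA interaction gave 0 to 1 (1 without BN44), and the TA and Paneth interaction 0 to 2, with 0 without BN45, BO25, BO27, BO57, BP03 or BP04 and 2 others in place of Cyp2c55 without BN44. Control stem against TA gave 249 to 801 genes (249 without BO27, 316 without BO58, 508 without BP03), Paneth against TA 2810 to 4259 (2810 without BP03, 2922 without BN44) and Paneth against stem 2870 to 4137 (2870 without BN44). List calls ran from 3 to 9 in stem (3 without BO27, 9 without BN44), 6 to 11 in TA (11 without BO25) and 3 to 11 in Paneth cells (11 without BN44, 7 without BO57). Setd1a ranged from -0.29 to 0.00 in stem, -0.01 to 0.33 in TA and -0.80 to -0.35 in Paneth cells.

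Some list calls by camera ended when 1 library was left out. In stem cells these were enterocyte markers without BO27 (adjusted p = 0.20) or BP03 (0.095), p53 targets without BN45 (0.052) and regenerative genes without BN45 (0.069) or BO27 (0.15). In TA cells they were p53 targets without BN45 (0.051) or BO25 (0.053) and unfolded protein genes without BN44 (0.066), BO57 (0.084), BP03 (0.30) or BP04 (0.11). In Paneth cells they were Paneth markers without BN45 (0.88), BO25 (0.065) or BO58 (0.52, direction reversed), ribosomal proteins without BO58 (0.57) and interferon genes without BO58 (0.054), BP03 (0.099) or BP04 (0.31). Paneth markers there ranged from 1.1e-06 to 0.88 and goblet markers from 0.032 to 0.98. Without BN44, goblet markers in Paneth cells passed (0.032), and without BO58 they passed with the direction reversed (0.035). Oxidative phosphorylation and ribosomal genes in stem cells, oxidative phosphorylation genes in Paneth cells and the other TA lists kept theirs. For named genes under the alternatives set beforehand, 2614 of 2638 values in stem, 2954 of 2970 in TA and 3220 of 3225 in Paneth cells kept their side of the threshold. In the same order, 7, 0 and 0 lost a call and 17, 16 and 5 gained one. No value with a call changed direction, and direction was not compared where neither setting made a call. Depth and spread limit what 4 libraries per group can show. On simulated data, 32% of genes changed 2-fold at a mean of at least 5 CPM were recovered in stem, 30% in TA and 8% in Paneth cells.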

Other observations

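Chosen after their results were seen were the split tests of DNA repair genes and mitochondrial ribosomal protein genes, the test of summed Rps13 copies, the GC test of ribosomal protein genes and the mixing test of stem cell markers.

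Mitochondrial ribosomal protein genes, a set picked after members appeared among the stem cell calls at 5 CPM, had 61 of 77 tested members of negative sign in hom stem cells, 12 of them lower at an unadjusted p under 0.05 and 4 adjusted over the set alone by edgeR. Their camera p was 1.7e-05, or 0.35 with an estimated correlation. In TA cells 48 were negative (camera p = 0.0043; 0.55 with an estimated correlation), and in Paneth cells 53 were positive (0.0022; 0.44). Chance was not excluded in stem cells: 8 of the 35 splits gave as large an absolute mean t (real 0.939, highest other 2.202). The other 7 leave at least 1 pair unparted; of the 8 splits that part all pairs, too few for a share under 0.05, the highest other was 0.553. With the replicate block the camera p was 9.9e-10.

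The 8 animals can be divided 4 against 4 in 35 splits, the real one included, and 8 of these part all 4 pairs of neighbouring codes; 8 are too few for a share under 0.05. For stem cells, 2 of 35 splits gave as many edgeR calls (real 2, highest other 5), 7 as many genes at an unadjusted p under 0.05 (1081; 2570), 2 as many by DESeq2 (277; 1184), 2 as many at 5 CPM (18; 65) and 27 as many lists (5; 12), so chance was not excluded by any. For TA cells the numbers were 8 for unadjusted p (942; 2188), 3 for DESeq2 (121; 690), 4 at 5 CPM (4; 8) and 25 for lists (7; 14). For Paneth cells they were 32 for unadjusted p (368; 1642), 28 for DESeq2 (27; 384) and 33 for lists (4; 15). Chance was not excluded for these TA and Paneth results either. Where the real split called 0 genes, all 35 of 35 splits give as many whatever the data, so the comparison says nothing: edgeR in TA cells (highest other 5), and edgeR (5) and edgeR at 5 CPM (5) in Paneth cells. Each of these values of 5, and that in stem cells, came from the split of the 4 females (BN44, BN45, BP03 and BP04) from the 4 males, which parts 0 pairs. The 5 genes were Xist, Ddx3y, Uty, Kdm5d and Eif2s3y in all 3 fractions, and every other split apart from the real one had 0 edgeR calls in stem and TA cells.

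The split with the most DESeq2 calls set BN44, BN45, BO25 and BO27 against the rest in all 3 fractions, with 1184, 690 and 384 genes, and the highest values at 5 CPM (65 in stem, 8 in TA cells) came from it too. It parts the earlier from the later codes and 0 of the pairs, so it points to a structure of the samples by code that the genotypes do not follow. Splits by sex or by code are therefore not chance splits, and the counts that only they reached neither exclude chance nor show it. Among the 8 splits that part all pairs, the highest other values were 0 edgeR calls, 30 DESeq2 calls and 0 calls at 5 CPM in stem cells, against 2, 277 and 18 for the real split. In TA cells they were 17 DESeq2 calls and 0 at 5 CPM, against 121 and 4. With the replicate block at 5 CPM, 1 of these 8 splits gave as many genes in stem cells (real 128, highest other 0) and 1 in TA cells (5; 0), which is too few splits for a share under 0.05.

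For the interaction of TA and Paneth cells 7 of 35 splits gave as many calls (real 1, highest other 2), so chance was not excluded. For stem and TA (real 0, highest other 2) and stem and Paneth (0; 9) all 35 splits must give as many, which says nothing. Among control libraries, 1 of 35 splits of each comparison gave as many genes, the real one: stem and TA 1013 (highest other 4), Paneth and TA 4721 (4), Paneth and stem 4600 (5). This excludes chance only if the libraries of an animal are taken as independent, and both fractions come from the same 4 animals. The 8 splits that part all 4 animals (highest other 0 in each comparison) are too few for a share under 0.05. Genotype effects in stem and TA cells correlated at 0.288 across genes, and 22 of 35 splits gave as high a value (highest other 0.718); both sets of libraries come from the same animals.

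For single lists, splits were compared by absolute mean t. For p53 targets 3 of 35 splits were as large in stem cells (real 0.742, highest other 0.946) and 3 in TA cells (0.793; 0.894), for oxidative phosphorylation genes in stem cells 3 (1.27; 1.72), and for ribosomal proteins in TA cells 3 (1.49; 1.75), so chance was not excluded. Of the other lists called in stem cells, 4 splits were as large for ribosomal proteins, 6 for regenerative genes and 14 for enterocyte markers. In TA cells the numbers were 2 for stem cell markers, 5 for S phase genes and 7 each for Wnt targets and unfolded protein genes. In Paneth cells they were 5 for oxidative phosphorylation genes, 11 for interferon genes, 15 for ribosomal proteins and 23 for Paneth markers. Chance was not excluded for any of these. For DNA repair genes 2 of 35 were as large in TA cells (0.769; 0.787), where chance was not excluded. In stem cells 1 of 35 was as large (0.622; 0.474), a share under 0.05 only if the pairs are ignored, for a list tested after its result was seen and at a camera adjusted p of 0.071, so chance is left open there too. Of the 8 splits that part all pairs, which are too few for a share under 0.05, the highest other value was 0.492 and 0.615 for p53 targets in stem and TA cells, 0.714 for oxidative phosphorylation genes, 0.858 for ribosomal proteins, and 0.413 and 0.604 for DNA repair genes. In stem cells 4 of those 8 were as large for enterocyte markers and 2 for ribosomal proteins. In Paneth cells 3 were as large for Paneth markers, 3 for interferon genes and 2 for ribosomal proteins. Whether the higher share of mitochondrial counts in hom stem libraries, in 4 of 4 pairs, bears on the stem cell lists was not tested.

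Rps13-ps2 had fewer and Rps13-ps1 more counts in hom than in het libraries of all 3 fractions. If reads moved between near-identical copies, their summed count would change much less than Rps13-ps2, and the ratio of log2 changes was 0.127 in stem and -0.227 in TA cells, so this candidate explanation stays open. Strain variants carried along with the targeted allele, which sits on the same chromosome as Rps13-ps2, could be behind it too: within 15 Mb of Setd1a, 10.2% of genes had an unadjusted p under 0.05 in stem cells, against 6.67% elsewhere and 9.08% at the 95th percentile of windows. Rps13-ps2 itself lies outside that window, while Rps13 (chromosome 7, 116331505 to 116334195) and its pseudogene copy Gm15483 (133738479 to 133738934) lie inside it. In TA and Paneth cells the shares of genes within 15 Mb lay at the 72.0 and 72.5 percentile of windows. The reads were not examined here, and an effect of Setd1a loss on the copies was not tested.

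The shift of p53 targets in stem and TA cells was set against 2 technical or compositional explanations. GC content or gene length as the whole cause is argued against, since the mean log2 fold change after a correction was 1.05 times that before in stem cells and 1.23 times in TA cells. A linear shift along the stem to transit-amplifying axis is argued against as the whole cause in TA cells, where removing a trend of slope 0.15 left 1.00 times the mean. The p53 targets tested there had a mean control log2 fold change of 0.08, stem minus TA. Such a shift could therefore move their mean little in either case. In stem cells a shift along the axis stays open: the slope was -0.01, so its removal moved almost nothing (1.08 times the mean). In both fractions the axis shares het libraries with the genotype comparison. With 3 of 35 splits as large in either fraction, chance stays open, and an effect of Setd1a loss on p53 targets is a hypothesis.

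In TA cells, more stem cells in the transit-amplifying gate may lie behind the rise of stem cell markers: an added share of 6.4% fitted on 50 other genes predicts 75.8% of the change in the 12 markers outside them, though the shared het libraries push that share upward. The same share predicts 12.5% of the rise of ribosomal protein genes, and a share of 57.1% that gave all of it would put Lgr5 at 93.7 CPM against 14.1 observed, so it is argued against as their whole cause. GC content or gene length is argued against for ribosomal protein genes in TA cells, whose mean after correction was 1.19 times that before. In TA cells that correction left 0.449 times the mean of unfolded protein response genes, so this explanation stays open for them. It left 0.736 times the mean of ribosomal proteins in stem cells, whose call held (camera adjusted p = 0.0010). The Notch pathway in TA and DNA repair genes in stem cells passed only after it (0.030 and 0.023). No outcome had been set beforehand for these lists. For ribosomal protein genes in TA cells a difference in library size was not decided. Totals of 35.1 ± 6.04 M in het and 30.4 ± 2.51 M in hom TA cells overlapped (26.57 to 39.76 M and 28.0 to 32.71 M). They gave an exact two-sided permutation p of 0.171. Chance (3 of 35 splits) stays open for these genes as well, and a change in the cells themselves was not tested.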
